A study of Mus musculus with 4 samples.

How the data were processed

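Messenger RNA was sequenced in 4 libraries from brown adipose tissue of male mice that had eaten a diet of 60% fat for 12 weeks and were fed ad libitum. Per the labels, 2 libraries came from mice lacking ATF4 in thermogenic adipocytes (KO 1 and KO 2) and 2 from wild-type mice (WT 1 and WT 2). The genotype label of each library set its group, and the number in each title set its replicate number. How ATF4 was deleted is not given in the sources used here.

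Per the labels' protocols, RNA was extracted with TRIzol, cleaned on an RNeasy column and made into libraries with a stranded TruSeq mRNA kit. Per the submitters' processing notes, kallisto 0.45.0 was used and the genome build was mm10. The transcript set, the strand setting and any trimming are not given in the sources used here. Per the file headers, the authors deposited for each library an estimated count and a TPM value (transcript abundance scaled to a total of 1e6) for each of 141450 transcripts. kallisto assigns reads to transcripts without aligning them to the genome and splits reads that fit several transcripts by expectation maximisation. For this reason 87.9 to 89.0% of the non-zero deposited estimated counts were not whole numbers, and genes with near-identical copies are uncertain. In each library all 67529 transcripts over 1000 bases had an effective length 199 bases below their length. The effective lengths of these transcripts therefore carried no difference between libraries, and those of shorter ones were not checked.

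Transcripts were assigned to genes with the GENCODE vM21 annotation (GRCm38, the assembly of mm10) by their Ensembl identifier without its version. In all, 138191 transcripts (97.7%) were matched, and the 3259 unmatched ones held 0.992 to 1.04% of each library's counts and stayed out of library sizes and tests. Estimated counts were summed per gene and rounded to whole numbers. The deposited TPM values were summed per gene and used only in an alternative test. Coordinates are those of GENCODE vM21.

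The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the 4 libraries, with TMM scaling, genotype as the sole term and genes kept by filterByExpr (minimum count 10, minimum total count 15). Adjusted p-values are Benjamini-Hochberg values over the 15643 genes tested, with a threshold of 0.05. Fold changes are KO over WT on the log2 scale, with a standard error (SE) taken from the fitted change and its F statistic. CPM (counts scaled to a total of 1e6) used TMM-scaled library sizes. The labels do not say whether each library comes from a separate animal, so the p-values measure the spread between these 4 libraries.

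The 34 gene lists were fixed before the data were examined and were tested with camera (preset correlation between genes of 0.01) where at least 3 members were measured, which left 33. Camera with a correlation estimated from the data and fry, a rotation test of a list by itself, were run beside it. Genes named in the text followed a rule fixed at the same time. It took 11 genes around ATF4 in any case, then up to 10 genes with the largest rise and up to 10 with the largest fall among called genes whose groups did not overlap and whose mean log2 CPM was at least 1, without pseudogenes and predicted genes, and then up to 4 members with the smallest p of each list described. Any other gene is said to have been chosen after its values were seen. A further list of 132 skeletal muscle genes in 4 categories, which takes in the fixed one, was compiled after the called genes were seen.

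The library names in the labels start with S1 (WT 2 and KO 1) or S2 (WT 1 and KO 2). What the prefix stands for is not given in the sources used here. Each prefix holds 1 library of each genotype, so a fit with the prefix as a block was planned. That fit leaves 1 residual degree of freedom. Its SEs and p-values, for genotype and for prefix, therefore rest largely on variation pooled across genes. Differences within each prefix are printed as log2 CPM with a prior count of 2. A gene at 0 counts in a group has a fold change bounded by 3 counts over that group. Ratios over 1 to 3 counts have an exact 95% interval. Bounds and intervals cover counting error only.

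Alternatives were DESeq2 size factors, no filter, a minimum of 1 CPM in 2 libraries, the replicate number as a block, the prefix as a block, leaving out each library, an offset for transcript length, robust empirical Bayes, leaving out mitochondrial genes and the 10 most abundant genes, a threshold of 0.1, DESeq2 1.42.0, limma-voom and limma on log2(TPM + 1) (limma 3.58.1). Leaving out the skeletal muscle genes, with and without the prefix as a block, was chosen after seeing the data, as was adjusting p over the genes outside the muscle lists alone.

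The tests were tried on simulated counts with the means and library sizes of these libraries and dispersions from their trend over expression. Genes were drawn independently, with no prefix effect, no dispersion of their own and no correlation between genes. The simulations therefore do not show how the tests behave where these are present. Of 15336 simulated genes tested in KO against WT, 22% of the genes changed 2-fold were recovered, 78.3% of those changed 4-fold and 92.5% of those changed 8-fold, with 4 false among 110 calls. In a second simulation camera found the 1 list shifted by 1.5-fold and called 0 of the others. In another, of 15277 genes with no change, 0 were called.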

Results

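From brown adipose tissue, 2 RNA-seq libraries of mice lacking ATF4 in thermogenic adipocytes (KO) and 2 of wild-type mice (WT) were compared after 12 weeks of a 60% fat diet. Brown adipose tissue burns fuel to make heat, and ATF4 is a transcription factor that raises amino acid synthesis and stress genes when the integrated stress response is active. The total estimated counts were 32714456 in WT 1, 34813870 in WT 2, 25985367 in KO 1 and 30405113 in KO 2. Between 21987 and 23151 genes had at least 1 count in a library. The 13 mitochondrially encoded protein genes took 33.0% and 32.7% of the counts in WT and 38.0% and 31.9% in KO. The first principal component of log CPM held 58.0% of the variance and separated the genotypes, and the second held 30.1% and separated the library name prefixes. The groups did not overlap for 26.3% of the tested genes, against 33.3% by chance with 2 libraries a group. A gene separated by prefix must overlap between genotypes, and the prefixes did not overlap for 53.2% of the genes. The 26.3% therefore does not show a genotype difference weaker than chance.

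The targeted gene checks the labels. Atf4 (ENSMUSG00000042406, chromosome 15, 80255184 to 80257541, plus strand, GRCm38) was at 24.97 CPM in KO 1 and 24.5 in KO 2, against 107 in WT 2 and 29.2 in the library labelled WT 1. Both KO libraries were therefore below both WT libraries, but WT 1 held 118% of the KO mean and 27.4% of the WT 2 level, so Atf4 does not by itself set the library labelled WT 1 apart from KO. The mean was 67.9 ± 54.8 CPM in WT and 24.8 ± 0.303 in KO (SD, n = 2 each). The log2 fold change of -1.46 (SE 0.57) did not pass the edgeR quasi-likelihood test (adjusted p = 0.9998, unadjusted p = 0.0453). It was -2.09 between the libraries of prefix S1 and -0.25 between those of S2, and adjusted p was 0.174 with the prefix as a block. Without WT 1 the log2 fold change was -2.11 (adjusted p = 0.000625), without WT 2 it was -0.24, and over all 17 alternatives adjusted p ranged from 2.08e-07 to 0.9999. The most abundant Atf4 transcript (ENSMUST00000109605) had 17.5 and 68.3 TPM in WT 1 and WT 2 and 13.5 and 15.2 in KO 1 and KO 2. Reads of other cell types in the tissue enter these values, and counts per exon were not analysed here, so a deletion of part of the gene would not be seen.

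**Figure D1:**
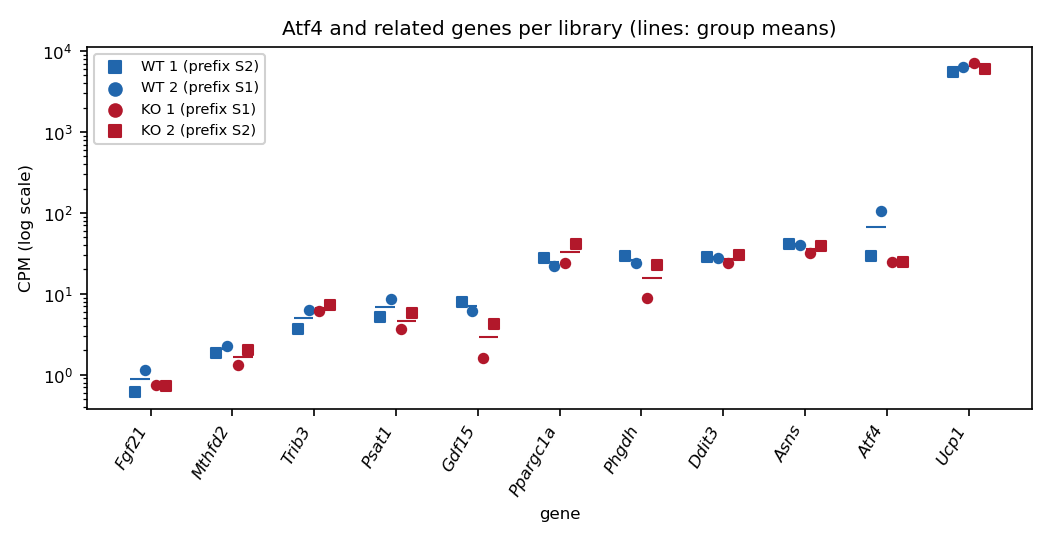
CPM (log scale) of Atf4 and 10 other genes fixed beforehand, for each of the 4 libraries (blue WT, red KO, circles prefix S1, squares prefix S2, lines group means). Atf4 is at 107 CPM in WT 2 and between 24.5 and 29.2 CPM in the other libraries, and Ucp1 is the most abundant of the 11.

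None of the 10 other genes fixed beforehand passed in the edgeR fit, and 1 of them, Gdf15, passed with the prefix as a block. Gdf15, a secreted factor raised by cell stress, was at 8.03 and 6.18 CPM in WT 1 and WT 2 and at 1.60 and 4.18 in KO 1 and KO 2, a log2 fold change of -1.29 (SE 0.46, adjusted p = 0.9998). In the fit with the prefix as a block it fell by 1.40 on the log2 scale (SE 0.28, adjusted p = 0.029). Without a block it ranged from -2.15 without KO 2 to -0.76 without KO 1. Fgf21, the other stress hormone examined, was near the detection limit at 0.605 and 1.14 CPM in WT and 0.742 and 0.720 in KO. Phgdh, the first enzyme of serine synthesis, was at 29.0 and 23.9 CPM in WT and 8.91 and 22.5 in KO, a log2 fold change of -0.75 (SE 0.42). The log2 fold change was -0.55 (SE 0.35) for Psat1, the next enzyme of that pathway, -0.31 (SE 0.36) for Mthfd2, a mitochondrial folate enzyme, and -0.21 (SE 0.18) for Asns, asparagine synthetase. With 1 library left out each time these ranged from -0.92 to -0.14 for Psat1, -0.65 to -0.04 for Mthfd2 and -0.35 to -0.07 for Asns, and from -1.57 to -0.23 for Phgdh. Ddit3 (CHOP) had -0.06 (SE 0.18) and Trib3, a pseudokinase induced with it, 0.41 (SE 0.31), with 0.08 without the library labelled WT 1 and 0.85 without WT 2.

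The fixed lists of ATF4-linked genes did not pass as groups in the fit without a block. Of 15 integrated stress response regulators 0 passed in edgeR, 1 had an unadjusted p under 0.05 and 0 passed in DESeq2 or limma. The list's median log2 fold change was -0.17 (camera adjusted p = 0.231, and 0.964 with an estimated correlation). It passed in 1 of 16 alternatives, without skeletal muscle genes and with the prefix as a block, chosen after seeing the data (median -0.18, adjusted p = 0.00833, range over the alternatives 0.00833 to 0.964). The 1 member was Atf3, a stress-induced transcription factor, at 26.9 and 10.2 CPM in WT and 4.14 and 8.29 in KO. With the prefix as a block Atf3 fell by 1.52 on the log2 scale (SE 0.18, adjusted p = 0.000604), and without a block its log2 fold change was -2.11 without WT 2 (adjusted p = 0.00107) and -0.72 without the library labelled WT 1 (adjusted p = 1.0). The 15 genes of serine, one-carbon and amino acid synthesis had a median of -0.21 (adjusted p = 0.47), the 20 cytosolic aminoacyl-tRNA synthetases one of -0.08 (adjusted p = 0.549) and the 10 amino acid transporters one of -0.18 (adjusted p = 0.484). Among the genes of these 3 lists 0 passed in edgeR, DESeq2 or limma, and 0 had an unadjusted p under 0.05.

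No identity gene of the brown adipocyte passed in the edgeR fit without a block, a fit that recovered 22% of simulated 2-fold changes. Ucp1, the uncoupling protein that makes heat, was at 5563 and 6295 CPM in WT and 7024 and 5989 in KO, a log2 fold change of 0.13 (SE 0.28, adjusted p = 0.9998). Ppargc1a, a coactivator of mitochondrial genes, was at 27.9 and 22.1 CPM in WT and 24.3 and 41.6 in KO, with 0.40 (SE 0.29). The 20 thermogenic genes had a median log2 fold change of 0.10 (range -0.87 to 0.55, camera adjusted p = 0.919), with 0 past the threshold in edgeR, DESeq2 or limma and 1 at an unadjusted p under 0.05. That gene was Dio2, which makes active thyroid hormone, at 113 and 80.9 CPM in WT and 36.9 and 68.8 in KO. It fell by 0.92 on the log2 scale with the prefix as a block (SE 0.16, adjusted p = 0.0132), and without a block ranged from -1.39 to -0.49 with 1 library left out. Genes of respiration had medians of 0.11 (56 nuclear genes, adjusted p = 0.572) and 0.13 (13 mitochondrial genes, adjusted p = 0.502).

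Across all genes the difference between the genotypes was led by skeletal muscle genes. Many of them were near 0 in both WT libraries and plainly present in both KO libraries. Of 15643 genes tested with edgeR, 122 passed, 120 of them higher in KO and 2 lower, and 629 had an unadjusted p under 0.05. All 120 were higher in KO within both prefixes, and 103 were under 1 CPM in both WT libraries and over 1 CPM in both KO libraries. Of the 120, 95 were in the skeletal muscle lists, most of which were compiled after the calls were seen and are not independent evidence of their direction.

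Genes of the contractile apparatus had the largest rises. Myh4, the myosin heavy chain of the fastest muscle fibres (ENSMUSG00000057003, chromosome 11, 67238029 to 67260446), was at 0 counts in WT and at 520 and 615 CPM in KO, at least 12965-fold higher (adjusted p = 0.000685). Myh1, another fast myosin, was at 0.0956 and 0.0817 CPM in WT and 297 and 262 in KO, a log2 fold change of 11.57 (SE 0.31, adjusted p = 0.000391). Acta1, skeletal muscle actin, went from 0.261 ± 0.0540 to 560 ± 148 CPM (SD, n = 2 each), a log2 fold change of 11.03 (SE 0.41, adjusted p = 0.000391). Tnnt3, the fast troponin T, rose by 11.34 on the log2 scale (SE 0.37) and Atp2a1, the calcium pump of fast fibres, by 11.23 (SE 0.43). Mylk2, the muscle myosin kinase, was at least 270-fold higher, the actin-binding Xirp2 at least 681-fold and Lmod2 at least 172-fold, each with 0 counts in WT. The myosin-binding proteins Mybpc1 and Mybpc2 had 1 count in WT, and their ratios were 4523-fold (95% exact interval 811 to 178690) and 2891-fold (518 to 114230).

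The list of 18 skeletal muscle markers fixed before the data were examined rose as a group. Of its members 17 passed over all genes tested and 18 adjusted over the list alone, with a median log2 fold change of 9.82, which was the same with the gene at 0 counts in WT set to its bound. The troponins Tnnc2 and Tnni2 rose by 9.82 (SE 0.32) and 9.83 (SE 0.33). The member that did not pass over all genes was Mb, myoglobin, chosen after its values were seen, at 1.05 and 13.4 CPM in WT and 112 and 61.0 in KO (adjusted p = 0.77, and 0.000598 with the prefix as a block). The call of camera was not kept with an estimated correlation (adjusted p = 0.0562), and fry gave an adjusted p of 0.00853. In the categories compiled later, 46 of 60 sarcomere genes rose, 18 of 28 genes of excitation and calcium handling, 10 of 12 of muscle energy metabolism and 21 of 32 of turnover and regulation, and 0 fell. The 18 fixed genes held 0.00038% and 0.00178% of gene counts in WT 1 and WT 2 and 0.339% and 0.296% in KO 1 and KO 2. All 132 muscle genes together held 0.0512% and 0.0576% in WT 1 and WT 2 and 0.600% and 0.503% in KO 1 and KO 2.

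**Figure D2:**
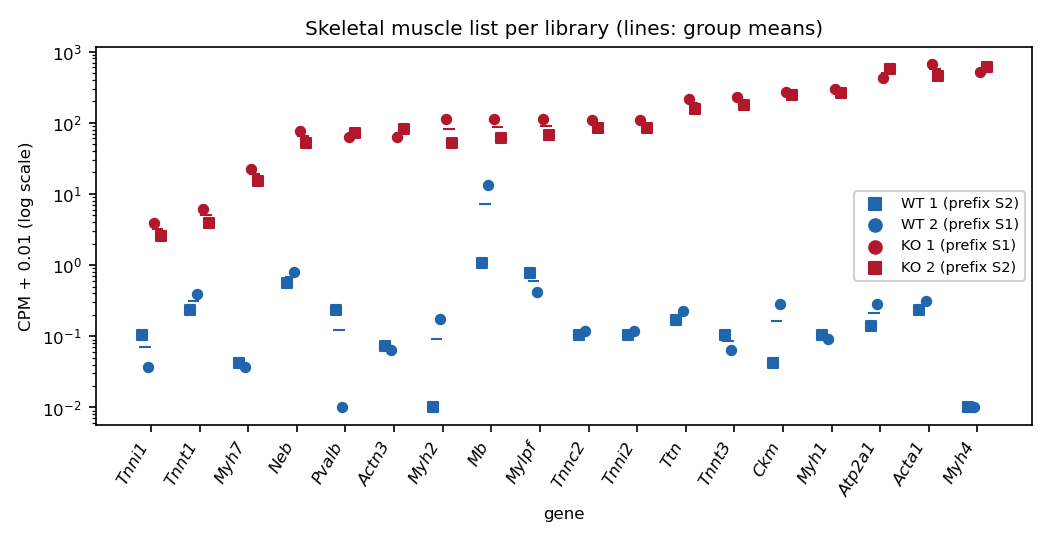
CPM + 0.01 (log scale) of the 18 genes of the fixed skeletal muscle list for each of the 4 libraries (blue WT, red KO, circles prefix S1, squares prefix S2, lines group means), in order of their KO mean. All 18 lie above both WT libraries in both KO libraries, and Mb has the highest WT value, 13.4 CPM in WT 2.

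The other 25 genes that rose included further genes of low WT level. H19, an imprinted long RNA and the called gene outside the muscle lists with the smallest p, was chosen after its values were seen. It was at 0.350 and 0.272 CPM in WT and 31.5 and 29.3 in KO, a log2 fold change of 6.60 (SE 0.24, adjusted p = 0.000391). With the skeletal muscle genes left out before scaling, an alternative chosen after seeing the data, H19 was the 1 gene called among 15511, with 502 at an unadjusted p under 0.05. The other 26 calls outside the muscle lists kept their fold changes, with no move over 0.00489 on the log2 scale and SEs of 0.996 to 1.002 times the former. Those calls ended through the adjustment, since the p-values of the first fit adjusted over the genes outside the muscle lists alone also left 1. With the prefix as a block as well, 158 genes passed, 104 higher and 54 lower in KO, 27 of them among the 122. None of the genes that fell met the rule for naming, so the 2 that fell are named after their values were seen. Fam177a was at 63 counts in each WT library and 0 in both KO libraries, at least 33.8-fold lower (adjusted p = 0.034), but its near-identical copy 1700047I17Rik2 on the same chromosome 12 had 1075, 1090, 689 and 1115 counts in WT 1, WT 2, KO 1 and KO 2. Summed over both copies the level was 36.3 and 31.4 CPM in WT and 26.9 and 38.2 in KO, so the call for Fam177a is uncertain. Gm48128 (log2 fold change -7.16, SE 0.95, adjusted p = 0.0461) is a processed pseudogene, whose reads can come from its parent gene. Neither passed without KO 2, nor Gm48128 without KO 1, although the fitted log2 fold changes with 1 library left out stayed within -8.92 to -8.71 for Fam177a and -9.71 to -6.23 for Gm48128.

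The count of changed genes depended on single libraries and on the prefix. It was 187 without the library labelled WT 1, 205 without WT 2, 116 without KO 1 and 78 without KO 2, of which 118, 119, 100 and 67 were among the 122. With the prefix as a block 320 genes passed, 246 higher and 74 lower in KO, including all 122, and 1389 had an unadjusted p under 0.05. These p-values rest largely on variation pooled across genes, since the block leaves 1 residual degree of freedom. Both KO libraries were below both WT libraries for 64 of the 74.

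By camera 4 other fixed lists were lower in KO, none of them with an estimated correlation, where adjusted p was 0.964 for each. The immediate early genes, which are switched on within minutes of a stimulus, had a median log2 fold change of -1.59 (adjusted p = 2.23e-10), with -0.76 within S1 and -1.65 within S2. Without the library labelled WT 1 the median was -0.70 (adjusted p = 8.69e-08). Of its 12 members 0 passed over all genes with edgeR, 10 fell adjusted over the list alone, 10 had an unadjusted p under 0.05, 2 fell in DESeq2 and 0 in limma-voom. With the prefix as a block 7 fell. Fos was at 51.0 and 4.85 CPM in WT 1 and WT 2 and at 0.977 and 2.50 in KO 1 and KO 2, so most of its difference lay in the library labelled WT 1. Jun was at 180 and 98.4 CPM in WT and 25.2 and 54.6 in KO. Dusp1, a phosphatase of MAP kinases, was at 194 and 124 in WT and 56.5 and 64.9 in KO, and Zfp36, which destabilises messenger RNAs, at 63.5 and 38.9 in WT and 23.6 and 26.6 in KO. With the prefix as a block the 4 fell by 3.65 (Fos, SE 0.37), 1.84 (Jun, SE 0.16), 1.36 (Dusp1, SE 0.17) and 0.99 (Zfp36, SE 0.17) on the log2 scale. Without WT 2, Fos, Jun and Dusp1 passed over all genes without a block (adjusted p = 1.49e-08, 0.00327 and 0.0187). Without the library labelled WT 1 their log2 fold changes were smaller and did not pass (Fos -1.47, Jun -1.30, Dusp1 -1.03). That of Zfp36 was also smaller there, at -0.63 against -1.03 with all libraries.

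White adipocyte markers had a median log2 fold change of -0.87 over 8 measured members (adjusted p = 0.00557), with -1.29 within S1 and -0.67 within S2. In edgeR 0 passed over all genes, 2 had an unadjusted p under 0.05 and 1 fell adjusted over the list alone, and DESeq2 called 2 and limma-voom 0. That 1 gene was Nnat, an imprinted proteolipid, at 59.0 and 64.3 CPM in WT and 22.6 and 35.5 in KO (adjusted p over the list 0.0475). Lep, which encodes leptin, was at 302 and 181 CPM in WT and 42.7 and 111 in KO, a log2 fold change of -1.65 (SE 0.50, adjusted p = 0.8). Mest, a marker of fat tissue expansion, was at 12.4 and 5.80 CPM in WT and 2.19 and 5.21 in KO, and Slc7a10, an amino acid transporter, at 7.26 and 16.1 in WT and 6.96 and 4.76 in KO. These 4 genes fell with the prefix as a block, Lep by 1.76 (SE 0.19, adjusted p = 0.000363), Mest by 1.32 (SE 0.21), Nnat by 1.12 (SE 0.20) and Slc7a10 by 0.92 (SE 0.20). Without a block, Lep and Mest passed when WT 2 was left out (adjusted p = 0.0238 and 0.0471) and Slc7a10 when the library labelled WT 1 was (adjusted p = 0.0451). Over the 4 libraries left out in turn, log2 fold changes ranged from -2.50 to -1.13 for Lep, -2.05 to -0.64 for Mest, -1.45 to -0.80 for Nnat and -1.46 to -0.31 for Slc7a10.

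Macrophage markers and genes of the extracellular matrix were lower in KO as lists, with differences that rested on single libraries. The 15 macrophage genes had a median log2 fold change of -0.73 (camera adjusted p = 7.68e-05), with -1.60 within S1 and -0.15 within S2. With 1 library left out this median ranged from -1.65 to -0.13, the latter without KO 1. Gpnmb, a gene of lipid-laden macrophages, was at 17.9 and 35.7 CPM in WT and 10.7 and 14.8 in KO, Trem2, a lipid-sensing receptor, at 2.90 and 3.27 in WT and 1.17 and 1.92 in KO, and Cd68, a lysosomal protein, at 13.96 and 24.7 in WT and 8.09 and 12.6 in KO. Without WT 2 the log2 fold change went from -1.07 to -0.49 for Gpnmb and from -0.90 to -0.43 for Cd68, and without the library labelled WT 1 Gpnmb passed (-1.49, adjusted p = 0.0253). The 20 matrix genes had a median of -0.44 (camera adjusted p = 0.000457), with -0.92 within S1 and -0.02 within S2. With 1 library left out this median ranged from -0.73 to -0.15, with -0.24 without KO 1 and -0.15 without WT 2. Col1a1 and Col1a2, the chains of type I collagen, were at 85.1 and 115 CPM in WT 1, 170 and 196 in WT 2, 58.2 and 73.9 in KO 1 and 77.5 and 102 in KO 2. Their log2 fold changes of -0.91 (SE 0.36) and -0.82 (SE 0.31) lay mainly in WT 2, without which they were -0.33 and -0.39. Dpt, a matrix protein of fibroblasts, had -0.75 (SE 0.26). In both lists 0 members passed over all genes in edgeR, DESeq2 or limma and 3 of each had an unadjusted p under 0.05. With the prefix as a block 1 macrophage gene fell, Ctss, and 2 matrix genes, Dpt and Col5a2 (without a block -1.98 to -0.38, -1.12 to -0.45 and -1.74 to -0.29 with 1 library left out), the names of Ctss and Col5a2 being chosen after their values were seen.

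In the other 28 lists tested, adjusted p was between 0.065 and 0.919, and of their 462 members 0 passed in edgeR, DESeq2 or limma without a block and 14 had an unadjusted p under 0.05. In the fit with the prefix as a block 3 passed, Atf3 and Dio2, given above, and the glycolytic enzyme Tpi1, chosen after its values were seen. Tpi1 was at 11.3 and 3.95 CPM in WT and 19.97 and 17.4 in KO and rose by 1.44 on the log2 scale in that fit (SE 0.32, adjusted p = 0.0497). Inflammatory cytokines came nearest, with a median of -0.81 (adjusted p = 0.065). Endothelial markers had a median of 0.27 (adjusted p = 0.214) and were higher in KO with the prefix as a block (adjusted p = 0.0224, and 0.985 with an estimated correlation). Medians of the other cell type lists were 0.33 for pericytes and smooth muscle, 0.57 for lymphocytes, 0.42 for erythroid cells and 0.08 for Schwann cells. Cell cycle genes had -0.36 and interferon-stimulated genes -0.10. Among metabolic lists the medians were -0.06 for the citric acid cycle, -0.01 for fatty acid oxidation, -0.05 for branched-chain amino acid breakdown, 0.03 for fatty acid synthesis, -0.08 for cholesterol synthesis, 0.03 for lipid droplets and lipid uptake and 0.11 for glycolysis. Stress and turnover lists had -0.06 for the mitochondrial unfolded protein response, -0.02 for that of the endoplasmic reticulum, 0.03 for the proteasome, 0.01 for NRF2 targets and 0.04 for mitochondrial dynamics. The 14 clock genes had -0.00036.

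**Figure D3:**
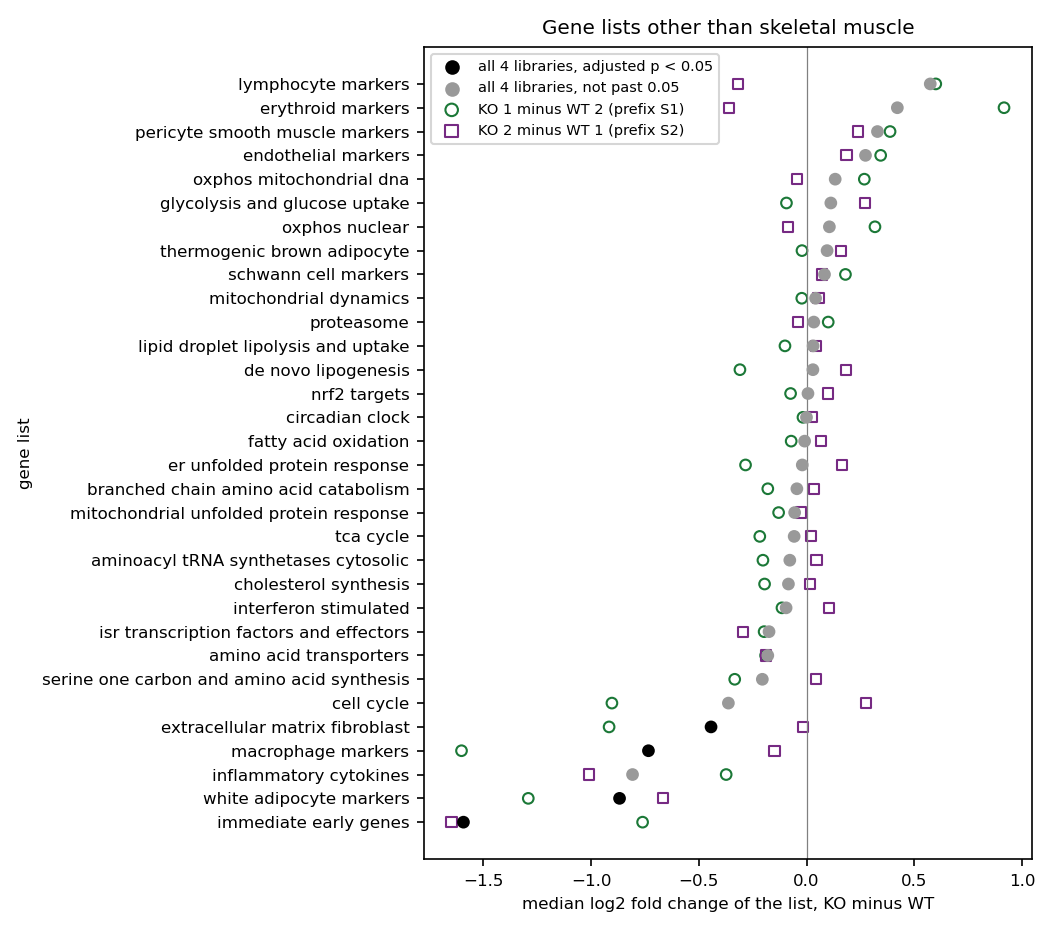
Median log2 fold change, KO minus WT, of 32 gene lists: filled circles over all 4 libraries (black where camera's adjusted p was under 0.05), open circles KO 1 minus WT 2 (prefix S1), open squares KO 2 minus WT 1 (prefix S2). Macrophage markers are at -1.60 within S1 and -0.15 within S2, and immediate early genes at -0.76 and -1.65; the skeletal muscle list, at 9.82, is left out.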

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

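The test of the transcripts below was chosen after the called genes had been seen. Transcripts with no match in the gene annotation take part in none of the comparisons reported. When they were added to the edgeR fit, 705 of 3259 had enough counts to be tested, 56 had an unadjusted p under 0.05, and 4 passed, all of them higher in KO. ENSMUST00000201001 was at 1.58 and 2.10 CPM in WT and 32.2 and 45.4 in KO, and ENSMUST00000239060 at 0 in WT and 20.1 and 11.6 in KO. Their genes are not given in the annotation used here.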

How the results depend on the processing

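Of the alternatives, leaving out the skeletal muscle genes, with and without the prefix as a block, was chosen after seeing the data, and the others were planned. Where a value below moved, the cause was not tested unless given.

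The 122 changed genes (120 higher, 2 lower in KO) became 457 (330 and 127) with no filter, 320 (246 and 74) with the prefix as a block, 210 (189 and 21) with DESeq2 and 1 (1 and 0) without skeletal muscle genes, where 502 had an unadjusted p under 0.05. In this last alternative the fold changes outside the muscle lists stayed (Fam177a -8.84, SE 0.86 before and -8.84, SE 0.87 after, adjusted p = 0.158; Gm48128 -7.16, SE 0.95 and -7.16, SE 0.94, adjusted p = 0.2), and calls ended because the 132 removed genes held most of the small p-values. The 2 lower genes became 5 with a threshold of 0.1, 1 with a minimum of 1 CPM in 2 libraries, 7 with the replicate block, 6 with limma-voom and 54 without skeletal muscle genes and with the prefix as a block (158 changed in all). Leaving out 1 library each time gave 78 to 205 changed genes, 74 to 176 higher and 4 to 29 lower, with the lone library of a genotype assumed to vary like the pair. Size factors, length offset, robust fit and omission of mitochondrial and abundant genes kept the total between 118 and 122. Of the 122, the length offset kept 109 and lost 13. Size factors kept all 122, and the robust fit and the omission kept 121 each.

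The Atf4 log2 fold change stayed negative, and leaving out 1 library gave -2.11 to -0.24. Among the alternatives with all 4 libraries it passed only with no filter (-1.46, edgeR adjusted p = 2.08e-07). There adjusted p also fell for other genes at almost the same fold changes, such as Fos (0.716 to 3.67e-46) and Myh4 (0.000685 to 2.46e-173). This pass is therefore not particular to Atf4. The 5 shifted lists became 0 with an estimated correlation, 1 with fry, 8 without skeletal muscle genes and with the prefix as a block, and 5 to 12 with 1 library left out. Leaving out 1 library reversed Fgf21 (-0.64 to 0.27, highest without WT 2), the serine list median (-0.355 to 0.0112, highest without WT 2), Ddit3 (-0.23 to 0.087, highest without KO 1), Ppargc1a (-0.040 to 0.73, lowest without KO 2) and the thermogenic list median (-0.0731 to 0.101, lowest without KO 2). None of these 5 reversed values passed.

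Among 15 named genes called in the fit on all libraries, 223 of 231 values kept direction and side of the threshold, and the 8 that no longer passed were for Fam177a and Gm48128. Among 28 named genes not called, 53 of 474 values passed and 3 changed sign.

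The replicate block gave 164 changed genes, 120 of them among the 122. Deviations of WT 1 and KO 1 from their group means correlated at -0.38 across genes. Those of WT 1 and KO 2, which share a prefix, correlated at 0.38. With 2 libraries a genotype, 1 value is the negative of the other by construction. Libraries of the same prefix thus deviated alike more than those of the same number. Whether the number also marks a pair cannot be read from these values. With 25985367 to 34813870 counts and 2 libraries a genotype, 22% of simulated 2-fold changes were recovered.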

Other observations

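The tests of explanations in this part were chosen after the values they bear on had been seen, and the fit with the prefix as a block was planned. The clearest pattern outside genotype followed the library name prefix. In the fit with the prefix as a block 491 genes differed between prefixes, 248 higher and 243 lower in S2, and the prefixes did not overlap for 53.2% of the tested genes, against 33.3% by chance. The clock output gene Dbp was at 45.4 and 51.8 CPM in WT 2 and KO 1 (S1) and at 3.76 and 3.19 in WT 1 and KO 2 (S2), a log2 difference of -3.80 (SE 0.18, edgeR adjusted p = 1.5e-05). Arntl, the core activator of the clock, went the other way, from 3.35 and 3.48 to 21.2 and 23.3 CPM (2.70, SE 0.17). Per3 differed by -1.78 (SE 0.17), Nr1d1 by -1.58 (SE 0.23) and Cry1 by 1.48 (SE 0.18).

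Single genes picked from those with the smallest p also differed between the prefixes. No list of antigen presentation genes or of these heat shock genes was tested. H2-Aa, Cd74 and H2-Ab1, which act in antigen presentation, were higher in S2, by 1.88 (SE 0.16), 1.65 (SE 0.16) and 1.55 (SE 0.15) on the log2 scale. The heat shock genes Hspa1a and Hspa1b, near copies that share reads, were higher in S2 by 3.35 (SE 0.29) and 3.14 (SE 0.30), with Hspa1a at 150 CPM in WT 1 and 35.2 in KO 2 against 22.3 in WT 2 and 1.84 in KO 1. These genes were also lower in KO within each prefix, by 2.68 (SE 0.29) for Hspa1a and 2.58 (SE 0.30) for Hspa1b in the fit with the prefix as a block. Immediate early genes and macrophage markers, lower in KO as lists, were shifted between prefixes too. Their medians were 0.99 (camera adjusted p = 2.66e-12) and 0.96 (3.69e-08) higher in S2, each with 6 members past the threshold. White adipocyte markers and matrix genes, also lower in KO, were not shifted as lists (camera adjusted p = 0.364 and 0.19). The 16 genes of the citric acid cycle had a median of 0.54 higher in S2 and did not overlap between prefixes for 16 members (camera adjusted p = 2.24e-07). With an estimated correlation adjusted p was 0.858 for this list and for the immediate early and macrophage lists. The elongase Elovl3, a member of the thermogenic list, was lower in S2 by 2.16 (SE 0.20). That list was not shifted between prefixes (camera adjusted p = 0.978), with 1 member past the threshold higher in S2 and 3 lower.

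A difference in the time of day of collection is a candidate explanation of the clock pattern. It predicts that the 4 activator-phase genes (Arntl, Clock, Npas2 and Cry1) and the other 10 clock genes move apart, and all 14 had the sign of their arm. A library or sequencing batch alone stays open. The median absolute log2 difference of the clock genes, 1.19, lay at percentile 100 of 10000 random lists of like expression (highest 0.58), but 5 of 32 other fixed lists also exceeded that highest value, and random lists ignore correlation between genes. The genotypes did not overlap for 1 of the 14 clock genes and the prefixes for 12. This count cannot test genotype, since each prefix holds both genotypes and a gene separated by prefix must overlap between genotypes. The fitted genotype changes of the 14 genes ranged from -0.66 to 0.45 on the log2 scale, with a median of -0.00036. Collection times are not given in the sources used here.

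The skeletal muscle genes of the KO libraries may come from skeletal muscle carried along with the tissue. That all 18 genes of the fixed list lay above both WT libraries in both KO libraries is the pattern itself and does not decide between explanations. The fast myosins Myh1 and Myh4 made up 86.0% and 92.9% of adult myosin heavy chain counts in KO 1 and KO 2. The design argues against a batch named by the prefix. Each prefix holds both genotypes, and all 18 genes of the fixed list lay above WT within each. That 18 of 18 rose with the prefix as a block follows from this and is not a separate test. The list's median difference between prefixes was -0.36 against 9.82 between genotypes. A muscle gene programme in the ATF4-lacking adipocytes stays open. It cannot be told apart from carried-over muscle, because the difference follows the genotype label in all 4 libraries. Whether the label of WT 1 is right is left open below. If it is wrong, the muscle difference would not follow genotype. WT 2 held more of the fixed list than WT 1, at 0.00178% against 0.00038% of gene counts. Mb, whose values are given above, made up most of this difference. Of other members, Acta1 (0.223 CPM in WT 1 and 0.299 in WT 2) and Atp2a1 (0.127 and 0.272) were higher in WT 2. Myh1 (0.0956 and 0.0817) and Tnnt3 (0.0956 and 0.0544) were lower. The developmental myosins Myh3 and Myh8 made up 0.0366% of the adult ones in KO (95% exact interval 0.022 to 0.0572%), but adipocytes could use adult myosins. The regulators Myod1, Myog, Myf6 and Pax7 had 3, 5, 35 and 3 counts in KO 1 and 1, 3, 26 and 2 in KO 2. All of them had 0 counts in WT. These counts do not decide between carried-over muscle and a programme in adipocytes.

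The low Atf4 of the library labelled WT 1 has no decided explanation. A swap with a KO library is not decided by Atf4. The KO library with more Atf4 held 23.4% of the WT 2 level, but WT 2 is 1 library. If its Atf4 is unusually high for WT, as left open below, a swapped library would not stand out. A single wrong label stays open: outside the muscle genes WT 1 correlated with WT 2 at r = 0.981, above KO 1 (0.959, also of the other prefix) and KO 2 (0.979, same prefix), but no 2 libraries share genotype and prefix to give the spread of r. Higher ATF4 activity in the animal of WT 2 also stays open, as the 30 genes of the stress response and amino acid synthesis lists went both ways (17 higher in WT 2, median log2 difference 0.0806, quartiles -0.15 and 0.68) while Atf4 differed by 1.87. Gdf15, an ATF4 target, was at 8.03 CPM in WT 1 and 6.18 in WT 2.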
